A study of Vitis vinifera with 4 samples.

How the data were processed

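The series used DNA affinity purification sequencing (DAP-seq), in which a tagged transcription factor made outside the plant is mixed with naked genomic DNA fragments, and the fragments it retains are amplified and sequenced. Because the DNA carries no chromatin, an event marks a fragment the protein can hold in the tube, not occupancy in a living cell. The 4 libraries were 2 for MYBPA1 and 2 for pIX-HALO, the tag vector without a transcription factor. Both groups used DNA from young leaves of grapevine cultivar Pinot Noir, and the proteins were made with a HALO tag in rabbit reticulocyte lysate, per the labels' protocols.

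The data examined were 1 list of binding events for MYBPA1 in narrowPeak layout. Per the submitters' processing notes, fastp 0.21.0 and Bowtie2 2.0 were used. The event caller is given only by the name of the list, which names GEM. Its version and settings, the genome build of the coordinates, the control used in calling and the way the 2 MYBPA1 libraries entered the list are not given in the sources used here. The deposited list holds a display score, a signal value, a −log10 p and a −log10 q per event, all made by the authors. The display score rose linearly with the signal value (Pearson r = 0.9999 over the events) and was not used further. The signal value never falls below 22.0, has 1 decimal and has no stated scaling. The q column never falls below 2.0, so the deposited list ends at q = 0.01. A value of 999 stands for a p too small to write, and 15 events carry it. Numbers were written with decimal commas, which were read as decimal points.

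Each event was 201 bp wide in the list, and the middle base was taken as its centre. Coordinates are printed with the first base of a chromosome as position 1. Chromosome names ran from chr01 to chr19, plus chr00, the name used in grapevine assemblies for sequence not placed on a chromosome. Unless stated otherwise, tests used chr01 to chr19. No library totals were used here, so the depth behind the events is unknown, and no value could be set against the spread between libraries. All p-values below compare positions or events of 1 list with random placement or random assignment. They do not measure differences between replicates.

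Tests were planned before the data were examined. The planned tests of a MYB recognition motif, of enriched 7-mers, of event strength by motif, of promoters and of 22 gene lists needed the sequence and gene models of the build of the coordinates, which were not used here. The gene table at hand, from assembly ASM3070453v1, has no chr00 and could not be tied to these coordinates, so no event was given a gene. For the same reason chromosome lengths were replaced by the span from the first to the last event. As planned for that case, the 10 events of highest signal value are named by position. Other regions were named after their values were seen, as the extremes of each measure.

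Clustering was the share of events whose nearest neighbour lay within 1000 bp, compared with 999 random placements over the same spans (permutation test, one-sided). Counts per chromosome were compared with the spans by a chi-square statistic with 9999 Monte Carlo draws. The middle 33.3% of each span was tested across the 19 chromosomes by 100000 random sign flips (permutation test, two-sided). Medians of signal were compared by 9999 random reassignments (permutation test, two-sided), and shares of strong events by Fisher's exact test, two-sided. Intervals on shares are 95% Wilson intervals and intervals on densities are 95% Poisson intervals by the normal approximation. Both cover counting error only. The chi-square test had been planned against chromosome length, and its use with spans was decided after the list had been seen. All other tests but clustering were added after that as well, together with the distance bands, the top 1% and the window classes they use. The alternatives were the 50% of events with the highest signal, events with −log10 q of at least 5, leaving out events within 200 bp of a stronger one, adding chr00, neighbour distances of 500 and 5000 bp and, added later, random placement within windows of 1 Mb or 100 kb, the latter also without close neighbours and for gaps and groups, and for chr00 a top 5% and 0.1% and events of each 100 kb window counted once.

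The clustering test was tested on simulated data for chr01 to chr03. It called 4% of 100 sets of uniformly placed events and 100% of 100 sets with 5% added neighbours. These sets had an even regional density and used fewer random placements per test than the real list. The check therefore does not show how often uneven regional density alone, as in the real list, would be called clustering. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.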

Results

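Binding sites of MYBPA1, a grapevine MYB transcription factor known as a regulator of proanthocyanidin (condensed tannin) synthesis, were mapped on naked Pinot Noir leaf DNA by DAP-seq. The design held 2 MYBPA1 libraries and 2 libraries of the empty HALO tag, the control that identifies DNA retained without a transcription factor. The outcome examined was 1 list of 30318 events at q = 0.01 or below, of which 29836 lay on chr01 to chr19 and 482 on chr00. There were no values per library, so no replicate error could be given. The signal value had a median of 49.1, a 25th percentile of 35.6 and a 75th percentile of 78.8. Of the events, 17763 (58.6%) had a −log10 q of at least 5.

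The first comparison was between chromosomes. Events were found on all 19 chromosomes, and chr18 held the most, with 2355 events or 7.89% of those on numbered chromosomes (95% interval 7.59 to 8.20%). Chr09 held the fewest, with 1128 events or 3.78% (3.57 to 4.0%). Relative to the span of its events, chr08 was the densest, with 84.2 events per Mb (80.5 to 88.0), and chr09 was the sparsest, with 49.1 per Mb (46.2 to 52.0). Chr17 had 76.6 events per Mb and chr01 had 74.6, whereas chr16 had 52.0 and chr19 had 54.7. Chr18, with the most events, also had the longest span (34.5 Mb), and its 68.2 events per Mb were near the 65.2 of the numbered chromosomes together. The 1.72-fold difference between chr08 and chr09 exceeded counting error, and the counts departed from proportionality to span (chi-square 543 with 18 degrees of freedom, Monte Carlo p = 0.0001, the smallest the draws can give). The draws and the intervals treat events as independent, although many stood in close groups, as described below, so they understate the spread. Chr00 had 17.8 events per Mb (16.2 to 19.4), 0.273 times the density of the numbered chromosomes together. Because chr00 holds unplaced sequence, neighbouring positions on it need not be neighbours in the genome. Its density and its windows are therefore not strictly comparable with those of numbered chromosomes.

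Within chromosomes, events were unevenly spread. The 449 full windows of 1 Mb held a median of 66.0 events, with quartiles of 46.0 and 86.0. The richest window was on chr05 from 3000001 to 4000000 with 122 events, followed by chr07 from 4000001 to 5000000 with 119. Windows of 116 events lay on chr11 and chr13, each from 1000001 to 2000000, and on chr18 from 5000001 to 6000000. At the other extreme, chr18 from 16000001 to 17000000 held 0 events, and the window before it held 4. Chr06 from 10000001 to 11000000 and chr19 from 14000001 to 15000000 each held 3. Chr02 from 11000001 to 12000000 and chr16 from 11000001 to 12000000 held 4 each. In all, 17 windows held at most 10 events, while the lowest window among Poisson draws with each chromosome's own mean held 22. The ratio of variance to mean of the counts was 11, against a mean of 2.24 and a highest value of 2.69 in those draws.

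The longest distance between neighbouring event centres was on chr18, from 15952039 to 17165488, a length of 1213 kb. Stretches of 1066 kb on chr12 (17272511 to 18338794), 1021 kb on chr02 (11324100 to 12345412) and 1008 kb on chr01 (13645515 to 14653361) followed. Gaps over 200 kb numbered 119, against a mean of 0.235 in random placements. Many sparse windows lay inside the chromosomes, and the middle 33.3% of the span held a mean of 27.1% ± 5.20 of a chromosome's events (SD over 19 chromosomes), compared with 33.3% under even spread (sign-flip permutation p = 0.00015). The share was below 33.3% on 15 of 19 chromosomes. It was lowest on chr07 at 18.7% and highest on chr17 at 36.7%. Chr08, chr10 and chr15 were the other chromosomes above it, at 36.3, 34.0 and 34.7%.

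**Figure D1:**
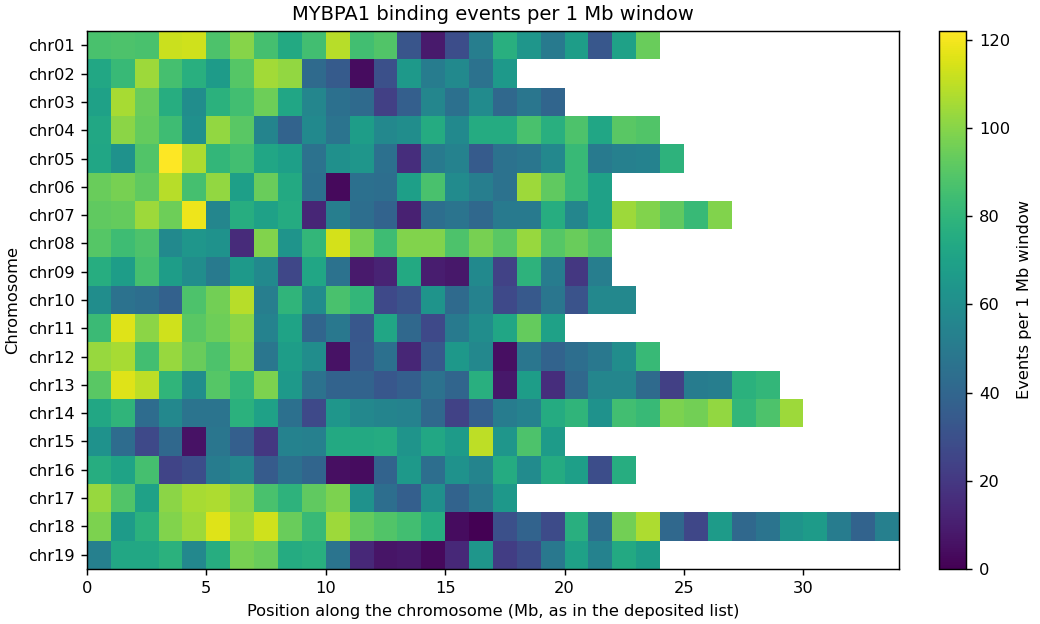
Number of MYBPA1 events in each full 1 Mb window (colour scale, events per window) along chr01 to chr19 (horizontal axis in Mb, coordinates as deposited, build not given). Dark windows inside chr18, chr06, chr19 and chr16 hold between 0 and 5 events, and the brightest, on chr05, holds 122.

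Events also stood in close groups. Of the events on numbered chromosomes, 8438 (28.3%, 95% interval 27.8 to 28.8%) had a neighbour within 1000 bp, against 12.4% ± 0.265 (SD of the random placements, highest 13.2%, permutation p = 0.001, the smallest the placements can give). Placing events at random within windows of 100 kb, which keeps the regional density, gave 15.5%. When events within 200 bp of a stronger one were left out, the share was 19.5%, against 14.6% in such windows and 11.8% over whole spans. The share per chromosome lay between 25.4% on chr15 and 31.4% on chr08.

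The excess was largest at short distances. Gaps of 100 to under 150 bp occurred 678 times against 97.6 at random, 6.95 times as often, and gaps of 50 to under 100 bp 4.13 times as often. Below 50 bp there were 57 gaps, 0.590 times the random number. The excess was 1.65-fold at 500 to under 1000 bp and 1.13-fold at 2000 to under 5000 bp. Against placement within windows of 100 kb, which keeps the regional density, gaps of 100 to under 150 bp were 5.35 times and gaps of 500 to under 1000 bp 1.31 times as frequent, and at 2000 to under 5000 bp there was no excess (0.970 times). The most frequent class of 10 bp among gaps under 400 bp was 120 to 129 bp, with 159 gaps, which is shorter than the 201 bp width of an event. Between neighbours at most 200 bp apart (1603 pairs), the stronger event had a median of 1.72 times the signal of the weaker (quartiles 1.31 and 2.59).

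Joining events at most 1000 bp apart gave 486 groups of 3 or more, compared with a mean of 116 and a highest value of 142 in 200 random placements, where single groups reached up to 6 events. With placement within windows of 100 kb the mean was 196, the highest value 228 and the largest single group 7 events. Events at most 200 bp apart overlap in the list and were counted separately. The groups were not recounted without such close events, so how many rest on them is not known. The largest group lay on chr04 from 20615225 to 20618061 and held 7 events, the strongest with a signal of 151. A group of 6 on chr08 from 12830494 to 12832438 included an event of signal 827. Another 6 events on chr12 from 1243173 to 1245536 were weaker, with a highest signal of 71.2. Groups of 5 with strong members lay on chr07 from 5112854 to 5114818 (highest signal 453) and on chr05 from 3993020 to 3995325 (426.5).

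**Figure D2:**
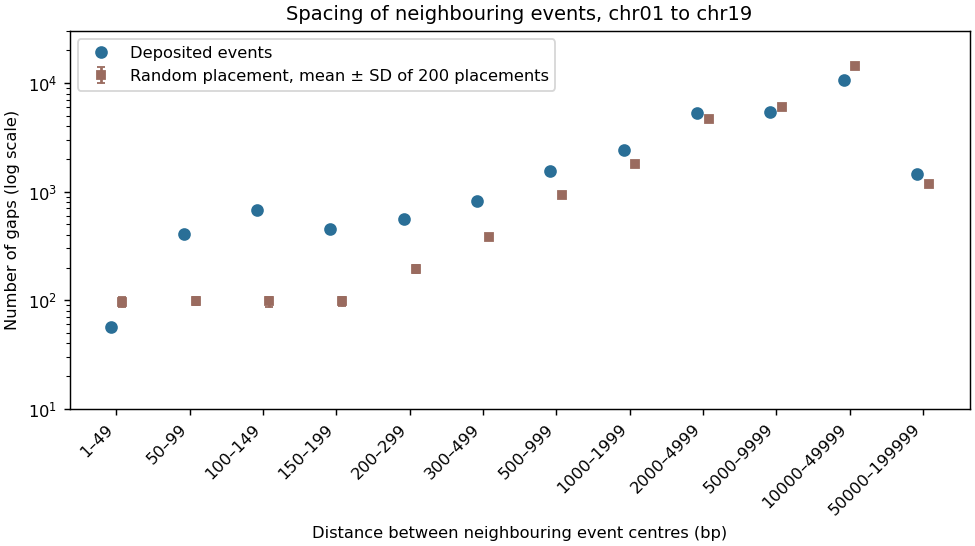
Number of gaps (vertical axis, log scale) between the centres of neighbouring events on chr01 to chr19 by gap length (horizontal axis, bp), with circles for the deposited events and squares for the mean ± SD of 200 random placements. Deposited gaps of 100 to under 150 bp number 678 against 97.6 at random, and gaps of 200 kb or more are not drawn.

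Signal values had a long upper tail. The strongest 303 events, the top 1%, had signals of 392 or more and carried 8.55% of the summed signal, and the stronger 50% of events carried 75.6%. The strongest event lay on chr10 from 16304558 to 16304758 with a signal of 4280, 87.2 times the median. The second lay on chr00 from 13733233 to 13733433 with 4061. The third was again on chr10, from 16328492 to 16328692, with 2938, and the fourth on chr00 from 18205889 to 18206089 with 2468. The next were on chr13 from 26112309 to 26112509 (1764.5), on chr08 from 15177604 to 15177804 (1730.5) and on chr00 from 7126175 to 7126375 (1724.5). Signals of 1594, 1312 and 1273 followed on chr16 from 2791856 to 2792056, on chr14 from 6354501 to 6354701 and on chr10 from 92902 to 93102. The first 9 of these 10 had a p at the limit of what the list can write. The event at 92902 on chr10 had a −log10 p of 255.

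Events on chr00 had a median signal of 49.9, close to the 49.1 of numbered chromosomes, but a longer upper tail. Their 95th percentile was 466, against 189. Of the 482 chr00 events, 31 (6.43%, 95% interval 4.57 to 8.98%) were in the top 1% of all events, against 272 (0.912%, 0.810 to 1.03%) of those on numbered chromosomes (odds ratio 7.47, Fisher's exact test, p = 2.63e-16). These 31 events lay in 12 windows of 100 kb, up to 6 in 1 window, so they are not independent. Counted once per window, 12 of 154 chr00 windows with an event (7.79%) and 241 of 4129 others (5.84%) held an event of the top 1%, an odds ratio of 1.36 that did not pass the threshold (Fisher's exact test, p = 0.296). Windows of chr00 hold fewer events each, which lowers their count in this comparison. Signal and p were not interchangeable. Among 324 events with a signal from 150 to under 160, −log10 p ran from 3.61 to 47.9 with a median of 31.8. An event on chr10 from 16234963 to 16235163, near the strongest of the list, had a signal of 411.7 and a −log10 p of only 7.73. An event on chr00 from 7126652 to 7126852 had 363.5 and 13.6. The nearest other events to these examples lay 85 and 477 bp away, in that order, so neither example stands alone.

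**Figure D3:**
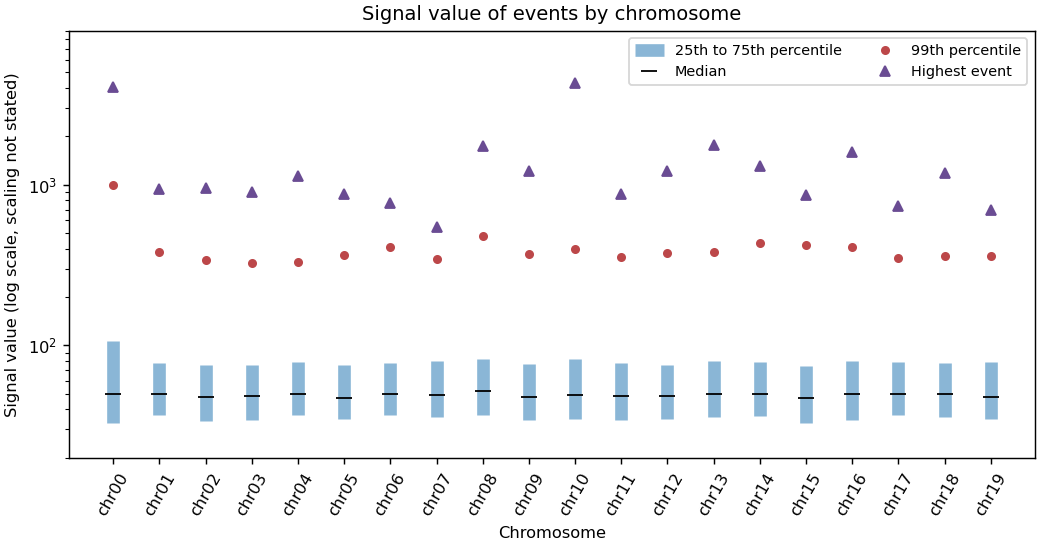
Signal value of events (vertical axis, log scale, scaling not stated) for chr00 and chr01 to chr19, with the range from the 25th to the 75th percentile as a bar, the median as a line, the 99th percentile as a circle and the highest event as a triangle. Medians lie between 46.9 and 52.0 throughout, and the 99th percentile of chr00 (995) stands above those of the numbered chromosomes.

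Signal was also compared with the distance to other events and with their density. Events 500 to 2000 bp from their nearest neighbour (6452) had a median signal of 50, and those over 20000 bp from it (1671) had 43.0, a difference of 7.0 (permutation p = 0.0001, the smallest the draws can give). The difference was 2.0 among the stronger 50% of events, with distances recomputed among those alone (permutation p = 0.128). This is a selection on signal itself that can lessen a difference in signal by construction. The relation was not monotonic. Median signal was 87.8 within 100 bp of the nearest event, 56.0 at 100 to 200 bp, 47.4 at 200 to 500 bp, 51 at 500 to 1000 bp, 49.7 at 1000 to 2000 bp, 49 at 2000 to 5000 bp and 47 at 5000 to 20000 bp. The bands compared were chosen after these medians were seen. Over the 423 windows of 1 Mb with 20 or more events, the count and the median signal of a window were positively correlated (Spearman's rho 0.298, Pearson's r 0.277, permutation p = 0.0001). The correlation is across windows of 1 list, and windows are not replicates. Within single chromosomes rho had a median of 0.263, was positive on 16 of 19 and ranged from −0.237 to 0.785. Over the 19 chromosomes, events per Mb and median signal gave rho 0.676 (permutation p = 0.00189) and r 0.615 (permutation p = 0.00458). Without chr08 and chr09, the 2 chromosomes farthest from the median density, rho was 0.574 (permutation p = 0.0175) and r was 0.410 (permutation p = 0.102). Both stayed positive, but r no longer passed the threshold. Leaving out the extremes of density narrows its range, which can lower a correlation by construction.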

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

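The alternatives to the clustering and chr18 results were planned, except random placement within windows, and all others were chosen after the results were seen. The excess of close neighbours over random placement kept its direction and stayed past the threshold under all 9 alternatives, with shares of 19.4 to 64.7% against 6.44 to 48.3% at random. The share of events on chr18 moved by less than its counting interval under all 4 alternatives (7.77 to 7.98%). Results added after the data were seen also held: chr08 over chr09 in density lay between 1.71 and 1.93, and the mean share in the middle 33.3% between 26.7 and 27.1%. An exception was the higher signal of events near another, which fell to a difference of 2.0 in the stronger 50% of events and no longer passed the threshold (permutation p = 0.128). This alternative selects on signal itself, which can lessen the difference by construction. Distances were recomputed within each alternative list, so the near and far events changed as well. The difference was 6.4 at −log10 q of at least 5, 8.0 without close neighbours and 7.15 with chr00. The odds ratio of chr00 among the strongest events lay between 3.63 and 22.9 under 5 alternatives, but fell to 1.36 with events of each 100 kb window counted once (Fisher's exact test, p = 0.296), since the events stood in few windows and chr00 windows hold fewer events. The planned motif, 7-mer, strength-by-motif, promoter and gene-list tests and their alternatives were not run, because they need the sequence and gene models of this build. Leaving out a replicate was not run either, since the list has no values per library. No paired analysis was possible because the list has no columns per library. The depth of the libraries is unknown, so it cannot be said which weaker sites were missed.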

Other observations

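All tests in this part were chosen after the list had been seen, and some were revised after a first result, as stated beside them. The spread of p among events of like signal was weighed as a trace of the control reads. For each event the control value was computed at which a one-sided binomial test with equal odds gives the deposited p for the deposited signal. For 80.0% of 15206 events with a whole signal and no neighbour within 1000 bp, that value fell within 0.05 of a whole number, against 10% by chance, 9.81% for events whose signal is not whole and 3.52% when each signal was raised by 1. The last comparison replaced a first one, which exchanged p within bands of 20 events of like signal and gave 70.4%. In that exchange 89.6% of events received p from an event of the same signal, with a share of 78.3%, and the 1586 others had 2.78%. A Poisson test against a whole expected count is argued against, since 7.92% of the means it needs were that near to a whole number. The 80.0% is consistent with a caller that set each event against scaled control reads, and the events off whole numbers stay unexplained.

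Of the whole control values above 0, 97.7% were multiples of 3.5 rounded up, where a step of that size covers 28.6% of whole numbers. The step was picked as the best of a series of steps, 3.45 did nearly as well, and the share is not corrected for that search. Over 11945 events with a whole control value of at least 1, the median control value was 11, or 3 steps. The median signal was 4.57 times the control (quartiles 3.14 and 8.0), under 3 times for 21.2% and over 10 times for 17.8%. Which control libraries were used was not tested. If q is the Benjamini-Hochberg value of p, a median of 39533 candidates was tested (95% of events gave 38822 to 40274), of which the list holds 76.7%.

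Among events of the top 1% for which a control value was computed, those on chr00 had a higher one than those on numbered chromosomes. The chr00 events of rank 2, 4 and 7 by signal had a p at the limit of what the list can write. No control value was computed for them. The excess in number of chr00 events in the top 1% did not pass the threshold with 100 kb windows counted once, a comparison in which chr00 windows hold fewer events each. Among events of the top 1% with a −log10 p under 300, 28 on chr00 had a median signal of 5.18 times the control (quartiles 3.77 and 10.1), against 39.8 times (26.2 and 66.4) for 258 on numbered chromosomes (permutation p = 0.0001, the smallest the draws can give). With isolated events and whole control values alone, the medians were 4.79 (9 events) and 35.4 (99 events), and with 1 median per 100 kb window they were 8.32 (12 windows) and 40.9 (232 windows, permutation p = 0.0001). A candidate explanation is sequence present in more copies than the assembly shows, since copies raise signal and control together. The median over all events was 4.67, but nearly all of those had a lower signal. It is therefore no comparison at like signal and does not decide on this explanation. Foreign or unassembled sequence drawn to chr00 would look alike and stays open, and no biological explanation was tested.

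Control values over 100 were computed for 45 events, 36 of them (80.0%) on chr00, which holds 1.59% of all events. Of these 36, 8 lay in 1 window of 100 kb, from 7100001 to 7200000, and all in 9 such windows. With isolated events and whole control values alone, 11 remained, 7 of them on chr00 and 3 in the chr10 stretch named next. Of the 9 others, 6 lay within 165 kb on chr10, from 16173968 to 16339373, a stretch that also holds the events of rank 1 and 3 by signal. Of the 10 strongest events, 5 had another event with a control value over 100 within 100 kb, against 0.412% of all events. These 5 are not independent, since ranks 1 and 3 share the chr10 stretch. The first 9 of the 10 strongest events had a p at the limit of what the list can write, so their own control values were not computed. The event of rank 10, on chr10 from 92902 to 93102, had a signal 12.1 times its control. The share of all events is no comparison at like signal, because an event can be listed with so high a control only if its signal is higher still. The limit of 100 was set after the values were seen.

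The 25% of 1 Mb windows with fewest events held a mean of 30.1 events, 69.3% fewer than the 98.2 in the 25% with most. At matched signal, the control values of isolated events were 11.2 in the sparse windows and 12.2 in the rich ones (difference −1.01, permutation of windows p = 0.001, the smallest the shuffles can give). That is 8.27% lower, but sites hidden by a higher background are not in the list, so this leaves that explanation open. Shrinking signal and control by that amount removed 3.38% of events in the rich windows with a limit on p alone. With the lowest listed signal as a floor as well, it removed 3.92%. An even loss of reads that removed 69.3% of them lowered control at matched signal by 77.6% without the floor (to 0.179 of the depth). With the floor, control was lowered by 61.2% (to 0.324 of the depth). Both are far more than the 8.27% observed. Loss of reads limited to sites that dropped out of the list stays open, as these calculations assume an even loss and the site strengths of the rich windows. The readings of these tests were changed after the values were seen, and assembly gaps, unplaceable repeats and fewer recognition sites stay open as well, with no biological explanation tested.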
